A study of Drosophila melanogaster with 2 samples.

How the data were processed

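Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos aged 0 to 24 h that carried Nf-YA fused to enhanced green fluorescent protein. Nf-YA is a subunit of NF-Y, a trimeric transcription factor that binds the CCAAT box. Per the labels, the fusion protein was precipitated with an antibody against the fluorescent protein, and chromatin was sonicated to fragments of 200 to 800 bp. The series held 1 group of 2 biological replicates, and the sex of the embryos was not collected. A control library named among the sources of the peak lists was not analysed here.

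The authors deposited peak lists in dm6 coordinates. The aligner, the peak caller and their versions were not given in the sources used here. Each replicate had a ranked list and a thresholded list, and the series had a pooled thresholded list and a conservative thresholded list made from both replicates. The peak signal is the authors' deposited value on a scale that the files do not state, and it was used to describe, rank and filter peaks within a list and to correlate the replicates across peaks. The deposited score encodes the irreproducible discovery rate, and the lowest score of each thresholded list corresponded to a rate of 0.01. The records of the thresholded lists name a further source file of unstated role. Reads and coverage were not analysed here, so the depth of each library is unknown. The ranked lists of the whole series hold 16 columns of values for inputs that are not named, and these columns were not used.

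Summits and peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X were analysed. Every peak of the lists used lay within the arm lengths of the reference sequence. Start sites came from the Ensembl annotation of build BDGP6.54, and transposable elements were left out. The pooled thresholded list was the main list. A gene was called bound when a summit lay within 500 bp of one of its start sites. Replicate overlap required at least 1 shared bp, and its chance level came from 1000 circular shifts of one list along each arm. The share of summits near start sites was compared with 1000 random placements on the same arms. These permutation tests were one-sided and could give no p below 0.001. The NF-Y motif RRCCAATSR and the other motifs of a list of 21 were sought on both strands within 50 bp of the summit and in a window of the same width 500 bp away, on 1 randomly drawn side per peak, with McNemar's exact test. Fisher's exact test, two-sided, compared motif shares between the top and the bottom 25% by signal, the bound share of 30 gene lists with that of all other protein-coding genes, and divergent with other genes. Divergent genes had start sites on opposite strands, pointing apart, within 1000 bp. An exact binomial test compared peaks per Mb on X and on the autosome arms 2L, 2R, 3L and 3R, without chromosome 4. Motif and list p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Intervals of shares are exact Clopper-Pearson intervals at 95%, and cover counting error only. The interval of the signal correlation came from 1000 bootstrap samples of peaks.

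The motifs, the gene lists, the tests and the rule for naming genes were fixed before the data were examined. After that, spellings of gene symbols were matched to the annotation. The rule named the genes at the 20 peaks of highest signal that overlapped a thresholded peak of each replicate, with a start site within 500 bp of the summit or else the gene that holds the summit. It always named 9 genes, the NF-Y subunits and genes linked to NF-Y. It also named the 2 bound members of highest signal from each list bound more often than other genes, and the bound members of lists bound less often where these were 3 or fewer. Alternatives were the conservative list, the own list of either replicate, the upper 50% by signal, merged peaks, other distances, windows, motif forms, backgrounds and chance models. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

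The code was tested on simulated data of 3024 peaks. The promoter share came out at 48.4% where 48.1% was expected, and the motif share at 21.3% against 20.8%. These expected shares were the share built in plus a background at random sites that the same code had measured. The motif share built in was far above that of the data. The replicate overlap came out at 70.4% where 69.0% had been built in. In the gene-list step, run on 13945 genes, the 1 list raised in the simulation was called and 0 other lists were called.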

Results

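The data were peak lists from ChIP-seq of an Nf-YA fusion protein in whole fly embryos aged 0 to 24 h, in 2 biological replicates of 1 group. The pooled thresholded list held 3354 peaks and the conservative list 3091. The own thresholded list of replicate 1 held 1793 peaks and that of replicate 2 held 2159, of which 2157 lay on the arms analysed. The depth of the libraries is unknown. The design has no second group, so the comparisons were between the replicates and between peaks and other parts of the genome.

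The replicates shared most of their tall peaks and fewer of their low ones. Of the thresholded peaks of replicate 1, 1362 of 1793 (76.0%, 95% interval 73.9 to 77.9) overlapped a thresholded peak of replicate 2. In the other direction 1342 of 2157 (62.2%, 60.1 to 64.3) overlapped. Circular shifts gave means of 0.914% and 0.767% (permutation p = 0.001 for each, the smallest 1000 shifts can give). In the top 25% by signal 98.0% of the peaks of replicate 1 and 98.1% of those of replicate 2 overlapped, against 46.4% and 26.2% in the bottom 25%. Of the pooled peaks, 1360 (40.5%) overlapped a thresholded peak in each replicate, and 950 (28.3%) overlapped one in neither.

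Peak signal, the authors' value, was correlated between the replicates over 3330 pooled peaks with an entry in both ranked lists. Spearman's rho was 0.642 (bootstrap interval 0.617 to 0.664) and Pearson's r of the log2 signal was 0.68. These are correlations across peaks, which are not independent replicates. The 2 unnamed inputs inside the ranked list of one replicate gave a rho of 0.596 in replicate 1 and 0.669 in replicate 2 over the same peaks.

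**Figure D1:**
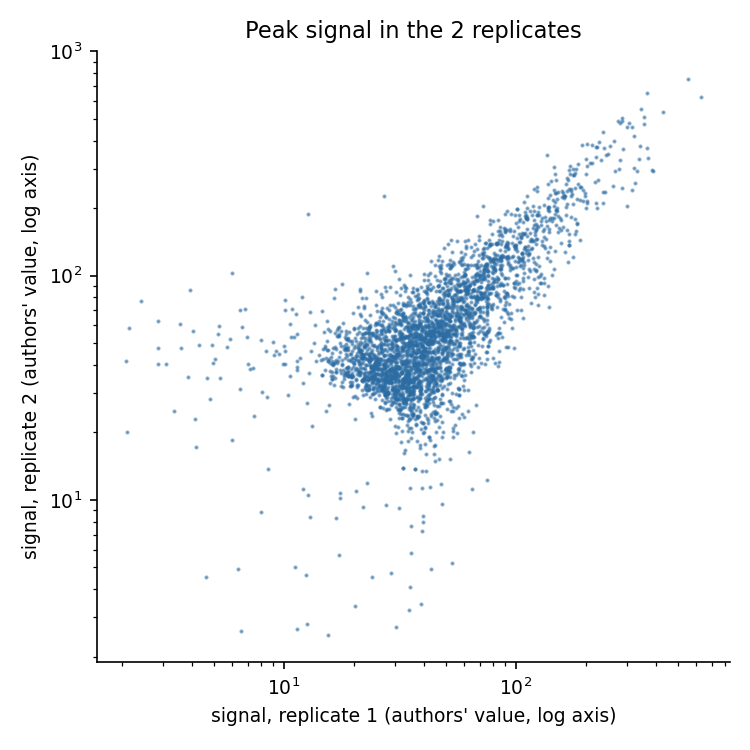
Signal of the 3330 pooled peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), each point 1 peak, in the authors' units. Signals rise together with a Spearman rho of 0.642.

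Nf-YA peaks were concentrated at promoters. Of the 3354 summits, 1561 (46.5%, 44.8 to 48.2) lay within 500 bp of an annotated start site, 3.42 times the 13.6% of random placements (SD 0.573, permutation p = 0.001, the smallest 1000 placements can give). Introns held 34.5% of summits against 39.3% at random, and intergenic sequence held 14.5% against 27.4%. Coding sequence held 2.21% of summits against 13.6%, and 3' untranslated regions held 0.686% against 4.40%. For these 4 classes the two-sided permutation p was 0.002, the smallest possible. The share in 5' untranslated regions away from start sites was close to random (0.716% against 0.779%, permutation p = 0.763). Each summit was counted in a single class, promoters first, so a high promoter share by itself lowers the other shares. Introns held 1157 of the 1793 summits outside promoters. Shares among those summits were not compared with random placements, so the intron and intergenic values do not show avoidance of these classes.

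**Figure D2:**
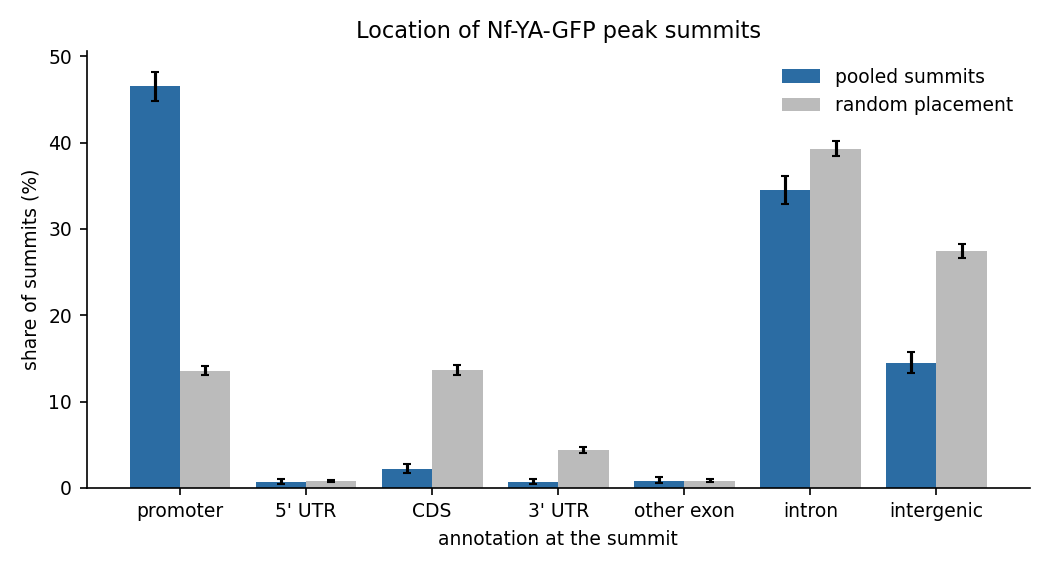
Share of the 3354 pooled summits in each annotation class (blue, with exact 95% intervals) and the mean of 1000 random placements (grey, with SD). Promoters, within 500 bp of a start site, held 46.5% of summits against 13.6% at random.

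The CCAAT box recognised by NF-Y was enriched at summits, but few summits held it. The motif RRCCAATSR lay within 50 bp of 84 of 3354 summits (2.50%, 2.00 to 3.09) and in 44 flanking windows (1.31%, 0.955 to 1.76), a ratio of 1.91 (McNemar's exact p = 5.2e-04). It was more frequent at tall peaks, in 38 of the 838 summits of the top 25% (4.53%) and 13 of the 838 of the bottom 25% (1.55%, Fisher's exact p = 5.1e-04). Among the 30 orderings of the 5 core bases, CCAAT had the largest excess of summits over flanks, at 1.19 percentage points, and the next ordering had 0.507, but by the ratio of summits to flanks, ranked after seeing the data, 3 rarer orderings stood above CCAAT (the highest, ACCTA, at 2.60, exact rank p of CCAAT = 0.133). The pentamer CCAAT without its neighbouring bases did not pass the test, at 19.5% of summits and 19.4% of flanks (McNemar's exact test, adjusted p = 1). With a window of 25 bp each side the difference between top and bottom was 1.19 percentage points and no longer passed the test (Fisher's exact p = 0.0845), and the excess over the flank did not pass after adjustment over the 21 motifs (exact test, adjusted p = 0.0543).

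**Figure D3:**
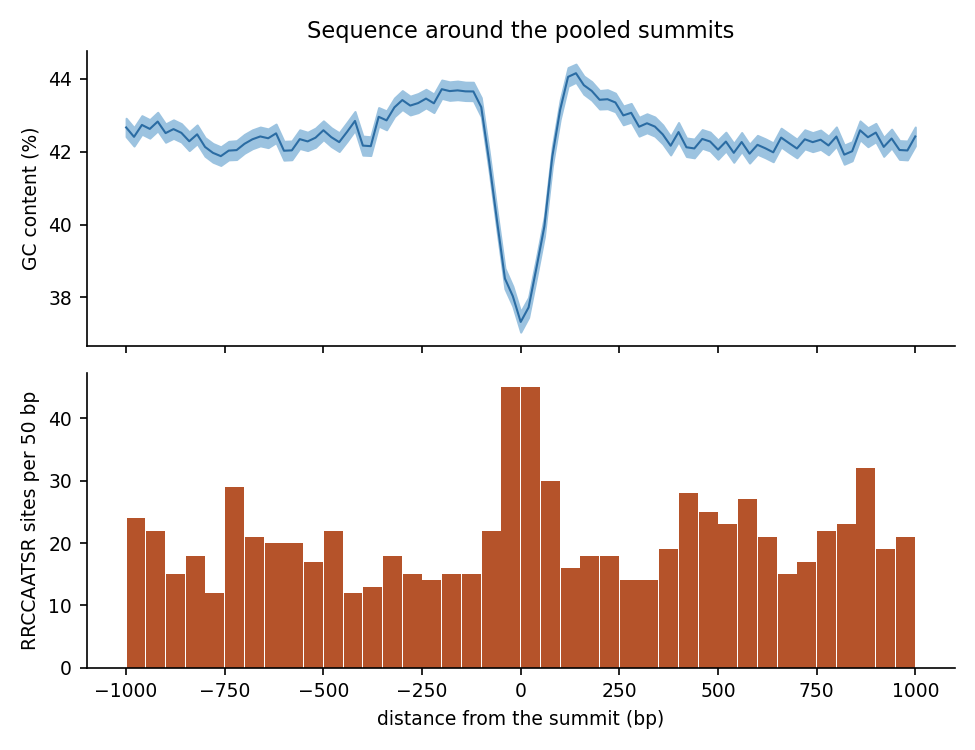
GC content in windows around the pooled summits (upper panel, mean with the standard error shaded) and the number of RRCCAATSR sites per 50 bp (lower panel), by distance from the summit in bp. The 2 bins next to the summit held 45 sites each.

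Of the 21 motifs, 7 differed between summits and flanks after adjustment, 6 higher and 1 lower. The TATA box, a core promoter element, was found at 7.01% of summits and 4.08% of flanks (McNemar's exact test, adjusted p = 5.3e-06). Sites of the insulator protein CTCF were found at 1.19% and 0.388% (exact test, adjusted p = 0.00282), and the core promoter element called Motif 7 at 2.86% and 1.76% (adjusted p = 0.0160). GATA sites (20.1% and 17.5%, exact test, adjusted p = 0.0284) and Exd-Hox sites (7.01% and 5.49%, adjusted p = 0.0347) were also higher, and the CACA repeat was lower (4.35% and 5.84%, adjusted p = 0.0269). The NF-Y motif had an adjusted p of 0.00361. Against flanks of matched GC content, chosen after seeing the data, NF-Y, CTCF and Motif 7 passed, TATA did not (exact test, adjusted p = 0.128), and GATA, Exd-Hox and CACA turned direction without passing. In the own list of replicate 1 alone 3 of the 21 motifs passed, and of the 7 above only NF-Y and TATA were among them. CTCF (exact test, adjusted p = 0.172), Motif 7 (0.729), GATA (0.0881), Exd-Hox (0.341) and CACA (0.278) did not pass there. Motif 7 also did not pass in the upper 50% by signal (exact test, adjusted p = 0.799).

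The tallest peaks lay mostly at promoters. Of the 20 tallest peaks found in both replicates, 17 were within 500 bp of a protein-coding start site, 4 held a CCAAT pentamer within 50 bp and 1 held the full motif. The tallest, on X with its summit at 2703886 (peak 2703749 to 2704028, signal 1299), lay 34 bp upstream of a start site of Ugalt, which encodes a UDP-galactose transporter. The next, on 3R with its summit at 4852531 (peak 4852322 to 4852766, signal 1266), lay 282 bp upstream of opa, a pair-rule gene. Peaks at CG14100 (1011), mRpL41 (892), PNPase (867), the Ssl1 and Chro pair (840), the CG7601 and CIA30 pair (789) and CG18549 (774) followed. mRpL41 encodes a mitochondrial ribosomal protein and Chro a chromatin protein. The peak at the Art3 and mRpS10 pair had a signal of 756, that at CenG1A and mRpS23 had 754, and that at px had 741.

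Peaks among the 20 also lay at caup (signal 739), a homeobox gene, at toy on 4 (721), a Pax6 gene, at scro (710) and at ap (689), both homeobox genes, and at the Polycomb group genes ph-p (770) and Psc (690). The caup peak, on 3L with its summit at 12609487, was the 1 with the full motif, GGCCAATGG at 12609514 to 12609522. The summit on 2L at 6612714 (signal 977) was in an intron of CG11050. The summits on 2R at 13035344 (788) and on 3R at 16222494 (762) were intergenic.

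Genes for cytosolic ribosomal proteins were bound far more often than other genes. A summit lay at 53 of the 91 (58.2%, 47.4 to 68.5), against 12.2% of the other protein-coding genes (odds ratio 10.1, Fisher's exact test, adjusted p = 8.3e-24). The own lists bound 41 of them in replicate 1 and 40 in replicate 2. Of the 53 summits, 50 were within 100 bp of a start site, with a median distance of 27 bp, and 1 held the NF-Y motif. The tallest were at RpS27 (signal 255, 3 bp downstream of the start site) and RpL7 (252, 21 bp downstream). Mitochondrial ribosomal protein genes were not past the test (13 of 73, exact test, adjusted p = 0.295).

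Genes that pattern the embryo and genes of chromatin were bound often. Of the segmentation genes 10 of 19 were bound (52.6%, exact test, adjusted p = 2.1e-04), with opa and the Wnt gene wg (signal 264) the tallest. The gap genes of this list, gt, hb, kni, Kr, tll and hkb, were not bound. Of the insulator and chromatin factors 8 of 14 were bound (57.1%, exact test, adjusted p = 5.1e-04), with Chro and ph-p the tallest. The Chro peak also lay at Ssl1, and the ph-p summit was 497 bp upstream of its start site, near the limit of 500 bp. Dref had the same signal (127) as the ribosomal protein gene RpL13, with a summit distance of 65 bp against 19 bp. Whether such summits belong to the listed gene or to a neighbour was not tested. Glial markers were bound in 5 of 8 cases (62.5%, adjusted p = 0.00516 by Fisher's exact test), among them moody (337), a receptor of the blood-brain barrier, and repo (203), a glial homeobox gene. Hox genes were bound in 4 of 8 cases (50%, adjusted p = 0.0333 by Fisher's exact test), among them Scr (180) and lab (139). Endoplasmic reticulum chaperones and genes of the unfolded protein response were bound in 7 of 19 cases (36.8%, exact test, adjusted p = 0.0198), among them Xbp1 (175) and Hrd3 (165). The list of cytosolic chaperones and heat shock genes was bound in 6 of 18 cases (33.3%, exact test, adjusted p = 0.0496), among them Hsp27 (375) and Hsp83 (233). Its bound members include Hsc70-5 (153) and Hsp22 (67.9), whose proteins are mitochondrial. When bound status was shuffled among genes with a like length of start-site windows, chosen after seeing the data, the last 4 lists no longer passed, with adjusted permutation p of 0.0750 for glia, 0.290 for Hox genes and 0.102 for each chaperone list. Neither chaperone list passed in the own list of either replicate, Hox genes did not pass in that of replicate 1 (Fisher's exact test, adjusted p = 0.0672), and glia did not pass in that of replicate 2 (37.5%, Fisher's exact test, adjusted p = 0.0820). The endoplasmic reticulum list was bound at 15.8% in replicate 1 and 26.3% in replicate 2. It did not pass in the conservative list (Fisher's exact test, adjusted p = 0.182), nor did the cytosolic chaperone and heat shock list (adjusted p = 0.296).

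Receptor, cuticle protein, cytochrome P450 and histone genes were bound less often than other genes. None of the 179 odorant and gustatory receptor genes was bound, an exact upper limit of 2.04% (adjusted p = 9.1e-10). Of the cuticle protein genes 2 of 110 were bound (1.82%, exact test, adjusted p = 5.7e-04), Cpr65Av (signal 71.7) and Cpr65Ea (58.2). Of the genes on the cytochrome P450 list 2 of 85 were bound (2.35%, exact test, adjusted p = 0.00913), Cyp6u1 (213) and Cyp310a1 (79.7). This list also holds Cyp1 and Cyp40, which are cyclophilin genes and not P450 genes, and both were unbound. The P450 list did not pass in the own list of replicate 1 (exact test, adjusted p = 0.0694) or replicate 2 (exact test, adjusted p = 0.203). Of the histone genes 1 of 115 was bound (0.870%, exact test, adjusted p = 6.2e-05), His2Av (119). Most histone genes stand in a cluster of near-identical repeats, so their values are uncertain. Among genes with a ranked peak the histone share was 25% (1 of 4) and did not pass (exact test, adjusted p = 0.697).

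The other lists did not pass the test. Bound counts were 11 of 54 translation factors, 4 of 13 muscle markers, 3 of 11 JNK pathway genes, 3 of 13 germline and maternal genes, 4 of 20 general transcription factors, 5 of 26 DNA replication genes, 5 of 32 splicing factors, 5 of 32 tRNA synthetases and 2 of 5 zygotic activators. They were 2 of 11 gut and fat body markers, 1 of 8 blood cell markers, 1 of 14 neuronal markers, 7 of 87 oxidative phosphorylation genes, 3 of 48 proteasome genes, 1 of 8 chaperonin genes and 3 of 27 genes of the G2/M cell cycle. Adjusted p values of these lists ran from 0.170 to 1.

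**Figure D4:**
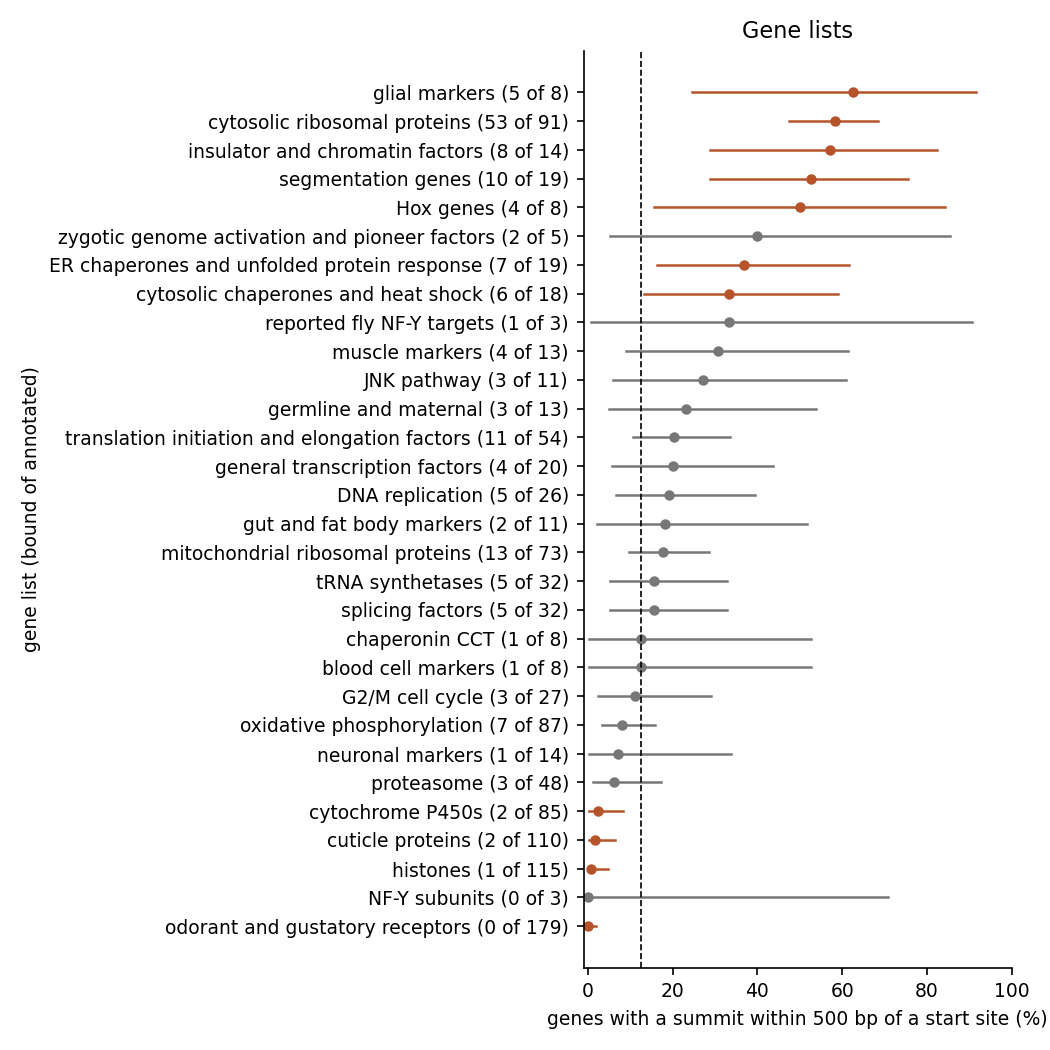
Share of genes of each list with a summit within 500 bp of a start site, with exact 95% intervals; orange lists passed the test and the dashed line is the share of all protein-coding genes. Cytosolic ribosomal protein genes stood at 58.2% and receptors at 0%.

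Of the genes linked to NF-Y, p53 was bound, 73 bp upstream of a start site on 3R with its summit at 23054155 (signal 85.8), and the peak was in the list of each replicate. None of the 3 subunit genes had a summit within 500 bp. The nearest summit was 3691 bp from Nf-YA, 22653 bp from Nf-YB and 16050 bp from Nf-YC. Nearest summits were 41933 bp from bsk, the Jun kinase gene, 2578 bp from sens, 19008 bp from the mitotic phosphatase gene stg, 3328 bp from the cyclin gene CycB and 11491 bp from the chaperone gene Hsc70-3. The summit nearest sens, on 3L at 13403703 (signal 153), held the full motif and was in the list of replicate 1 and not in that of replicate 2. Of the reported fly targets 1 of 3 was bound (Fisher's exact test, adjusted p = 0.470), and of the subunits 0 of 3 (Fisher's exact test, adjusted p = 1).

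Divergent genes were called bound more often than other genes. A summit lay at 994 of 5052 divergent genes (19.7%, 18.6 to 20.8) and at 743 of 8893 other genes (8.35%, 7.79 to 8.95), an odds ratio of 2.69 (Fisher's exact p = 7.7e-81). A summit between the start sites of a pair can count for both genes. With 1 gene drawn per connected set of divergent genes, a choice made after seeing the data, the odds ratio was 2.66 (Fisher's exact p = 3.3e-49). The drawn gene could still be called bound by a summit at the start site of its partner, so the draw does not remove this sharing. Having the start sites of both genes in reach can by itself raise the bound share of divergent genes. A gene with more start sites had more chances to be called divergent and to be called bound. Neither effect was tested for divergent genes.

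The density of peaks on X was not detectably different from that on the autosome arms 2L, 2R, 3L and 3R. X had 24.2 summits per Mb and these 4 arms 25.4, a ratio of 0.952 (exact binomial p = 0.298). Arm 2L had 27.2 per Mb (exact interval 25.1 to 29.4), 2R had 24.6, 3L had 26.4 and 3R had 24.0. The small chromosome 4 had 13 summits, or 9.64 per Mb (5.13 to 16.5).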

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

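Entries of the ranked lists outside the arms analysed were picked out because each count exceeded a floor of 3. Their absence had not been predicted. On the Y chromosome the ranked list held 18 of 96038 entries in replicate 1 and 149 of 116026 in replicate 2. On other scaffolds it held 308 in replicate 1 and 1092 in replicate 2. Most of these entries did not reach the thresholded lists, where 2 peaks of replicate 2 lay on such scaffolds. The sex of the embryos was not collected.

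The design names no second group, so no biological explanation was tested by a comparison of groups. The tests of the whole ranked lists, of gene-order rotation and of the proteasome and oxidative phosphorylation lists were chosen after the results were seen. Shorter motifs and other windows were planned as alternatives, but the limit for reading them as an explanation was written after the results were seen. Few summits held the NF-Y motif. Whether the motif or window was too narrow cannot be told apart from these values, because no limit was set beforehand and other motif forms were not tried; for the 3 forms and 3 windows tried on the pooled list, the largest excess over the unmatched flank was 1.43 percentage points, with 100 bp each side. GC content is argued against as the source of the excess, since against flanks of matched GC content McNemar's exact p was 6.8e-06. The 30 orderings of the core, which hold the same bases, were split. CCAAT stood first by excess (exact rank p = 0.0333), but 3 orderings stood above it by ratio (exact rank p = 0.133). Other effects of base composition therefore cannot be told apart from these values. Summits without the motif lay at start sites about as often as those with it (46.5% and 50%, Fisher's exact p = 0.580), so whether they are general promoter sites cannot be told apart from these values, because the motif-bearing summits were few.

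Summits were AT-rich, at 38.1% GC against 42.3% at 500 bp, a difference of -4.18 points (95% interval -4.70 to -3.67), but not at all signals: the difference was -7.68 points in the top 25% of peaks and +1.44 (0.454 to 2.43) in the bottom 25%. A preference of the libraries for AT-rich fragments cannot be told apart from binding to AT-rich sites, because summits were richer in AT at higher signal, as either would give. Over the whole ranked lists summits were richer in GC than 500 bp away, by 3.50 points in replicate 1 and 3.60 in replicate 2. These lists held 95712 and 114782 entries, most of which did not reach the thresholded lists. In the thresholded own lists the difference was -4.74 points in replicate 1 and -6.72 in replicate 2. The base composition of start sites is argued against as the whole cause, since unbound start sites at the same distances as 1445 summits had 2.12 points more GC (1.30 to 2.95). The 1793 summits not within 500 bp of a start site were AT-rich too, with a difference of -3.06 points (-3.69 to -2.42) from 500 bp away. Other causes were not tested.

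Genes of cytosolic ribosomal proteins were bound often. Clustering of bound genes along the arms is argued against as the source of the high count by rotation of bound status along the gene order (permutation p = 0.002, the smallest possible). The rotation cannot tell whether a summit at a ribosomal protein gene belongs to that gene or to its neighbour. Divergent promoters are argued against, since outside divergent pairs 15 of 35 were bound against 8.22% of other genes (Fisher's exact p = 3.9e-08). A build-up of signal at any strongly transcribed gene stays open, since transcription was not measured, although the proteasome and oxidative phosphorylation genes together were bound in 7.41% of cases against 12.5% of other genes (Fisher's exact p = 0.0872).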

How the results depend on the processing

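Alternatives on GC-matched flanks, ratios of reordered cores, low-signal entries, gene order, start-site windows and 1 gene per connected set of divergent genes were chosen after seeing the data. The promoter share (35.7% to 58.8%), the divergent odds ratio (2.10 to 2.78) and both replicate overlaps (67.9% to 83.0%, and 55.9% to 68.9%) kept their direction and side of the threshold under every alternative run. The CCAAT share kept its call in 12 of 14 alternatives and lost it with CCAAT alone (19.5%) and among orderings of the core ranked by ratio (2.50%, exact rank p = 0.133); with 25 bp each side it passed its own test (1.40%, McNemar's exact p = 0.00558) but not after adjustment over the 21 motifs (exact test, adjusted p = 0.0543). The excess in tall peaks kept its call in 9 of 10 and lost it with 25 bp each side (1.19 points). The ratio of X to autosomes, never past the test, turned above 1 with the conservative list (1.01) and the upper 50% by signal (1.05), and ran from 1.01 to 1.06 without either replicate. The correlation moved to 0.70 with the conservative list and 0.599 away from promoters. The 11 lists past the test became 7 among genes with a ranked peak, 7 with like start-site windows, 17 with shifted summits, and 7 without either replicate. Shifted summits also called the NF-Y subunits (0 of 3 bound, adjusted permutation p = 0.004), so calls under that setting, here and below, carry little weight. The 7 motifs became 4 with the conservative list, 1 with 25 bp each side and 3 with GC-matched flanks, and ran from 3 to 8 without either replicate. Turned in direction were Exd-Hox with 100 bp each side (11.8%), Exd-Hox (7.01%), GATA (20.1%) and CACA (4.35%) with GC-matched flanks, and histones among genes with a ranked peak (25%, 1 of 4). Smaller windows hold fewer sites, and fewer peaks bind fewer genes; otherwise the cause was not tested. Of the lists, ribosomal proteins, segmentation, insulator and chromatin factors, cuticle proteins and receptors passed under all 12 alternatives. Of the 47 named genes, those bound in the pooled list that became unbound were opa, ph-p, mRpS23, Cpr65Av, Cpr65Ea and Cyp310a1 within 250 bp of a start site; CG11050 (by a lower peak at its start site, signal 82.7, and not the tall peak in its intron), p53, Cpr65Av, Cpr65Ea and Cyp310a1 in the upper 50% by signal; CG11050 and Cpr65Ea without replicate 1; Cpr65Av, Cpr65Ea and Cyp310a1 without replicate 2; and Cyp310a1 in the conservative list. No paired analysis was possible because there is only 1 group. Depth is unknown and limits how far unbound genes can be read.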

Other observations

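Some tall summits with the full NF-Y motif are named here after their values were seen, and no class of genes was tested among them. On 4 a summit at 704516 (signal 505) lay at ey, a Pax6 gene, with AACCAATCA at 704511 to 704519. On 3L summits lay at the T-box genes Doc3 (signal 424, GACCAATGG) and Doc1 (336, AGCCAATCA), and on 2R at Sps1 and conv (402, AGCCAATCA) and at the homeobox gene unpg (328, GGCCAATGG). Of the motif-bearing summits as tall as that of unpg, 7 had no protein-coding start site within 500 bp, the tallest of them on 3R at 13877312 (signal 670). Low-signal entries stood beside taller peaks, since all 131 pooled entries with a signal under 20 had their summit within 500 bp of a taller one, at a median of 203 bp.

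The homeobox, Pax6 and Polycomb group genes at the tallest peaks raised a hypothesis that targets of Polycomb repression are bound often. A list of 30 textbook targets was written from memory before this test, but after the tallest peaks and the bound count of the segmentation list, which holds en, had been seen, and none of its genes was at the 30 tallest. The list held no Hox genes, which are also Polycomb targets and of which 4 of 8 were bound. The Hox genes did not pass the shuffle among genes with like start-site windows (adjusted permutation p = 0.290). The wording of the prediction on the tallest peaks was changed after the result was seen, and its threshold was not. Of the listed genes, 24 of 30 were bound (80.0%, exact interval 61.4 to 92.3), against 12.3% of other genes (odds ratio 28.5, Fisher's exact p = 4.7e-17). Without ey, Doc1 and unpg, named above, and without en 20 of 26 were bound (76.9%, Fisher's exact p = 7.7e-14). The own lists bound 21 in replicate 1 and 18 in replicate 2. A larger number of start sites per gene is argued against as the cause, since shuffling among genes with like start-site windows gave a mean of 15.8% and a highest share of 43.3% (permutation p = 0.002, the smallest possible). Both tests treated the listed genes as independent, though some lie near each other, such as mid and H15 on 2L. Bound status was not rotated along the gene order for this list, so clustering of bound genes was not tested. The bound genes included Dll (signal 431), tin (350) and pnr (292), and 5 of the 24 summits held the NF-Y motif. The enrichment is consistent with binding near Polycomb targets, and may equally reflect another feature that such genes share, since no other data on chromatin were used here.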
